A study of Nicotiana benthamiana with 28 samples.

How the data were processed

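The series compares gene expression of wild-type Nicotiana benthamiana seedlings and 6 mutant or construct genotypes after a mock or XEG1 protein treatment of 3 h. Per the labels' protocols, RNA of 12-day-old seedlings was extracted with an E.Z.N.A. total RNA kit, and libraries were prepared from 1.0 µg of total RNA with version 3.0 of the MGIEasy RNA library kit. The submitters' processing notes name HISAT2 version 2.0.4, a spliced read aligner. The genome build, the annotation and the step that turned alignments into TPM are not given in the sources used here; gene identifiers begin with Niben101. The authors deposited 1 list of TPM per library, a unit that divides reads by gene length and scales each library to a total of 1e+06, which was checked on each list. A combined file of all libraries was not used here.

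Samples were grouped by the genotype and treatment in the labels, with 2 libraries in each of 14 groups. Titles call the control EV and the treatment label calls it mock; both were taken as 1 control. The labels give replicate numbers but do not say that the replicates came from separate plants or growth batches, so p-values measure only the spread between these libraries. The replicate numbers were not treated as pairing the samples.

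The design fixed before the data were examined planned a count-based quasi-likelihood test. Because the values are TPM and not counts, the main test was instead limma's moderated test with a mean-variance trend and robust shrinkage on log2(TPM + 1), for the 36777 genes with a mean of at least 1 TPM over the 28 libraries. A single fit of 14 group means with 14 residual degrees of freedom gave all contrasts: XEG1 minus mock in each genotype, differences between these responses, and mock differences from wild type. Benjamini-Hochberg adjusted p-values under 0.05 were called, per contrast. Log2 changes are on the log2(TPM + 1) scale, which understates the change of genes of low abundance. Genes called in wild type formed a risen and a fallen set; their change in each other genotype was tested with limma's rotation test fry, adjusted over 12 tests, which asks whether the genes of a set move on balance in 1 direction. TPM keep no depth, so depth limits cannot be given. Some genes are listed at 0 in 1 library and well above 1 TPM in its replicate, so a listed 0 can be a failed estimate; for these genes library values are given and no fold.

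The genes named in each comparison were those with the largest change each way among called genes with a mean log2(TPM + 1) above 1 and both libraries of a group beyond both of the other, at most 2 each way because the identifiers came without names. A selection of these is printed. Gene lists by function, fixed before the data were examined, were not tested for the same reason. Genes named outside this rule were chosen after their values were seen, and this is said where they appear. Identifiers can belong to duplicated genes of this allotetraploid species, and how reads shared between copies were assigned is not given in the sources used here.

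Alternatives planned before the data were examined and run were a pseudocount of 0.1, no filter on low values (50297 genes above 0 in some library), a fit of only the compared groups, a replicate block, a log2 threshold of 1, set definitions with that threshold, and leaving out each library in turn. Where leaving out a library left 1 in a group, that library was assumed to vary like the other groups. Median-ratio scaling of libraries, a set of the 100 genes with the largest wild-type rise, and set tests of response differences were added after the data were examined. The risen set, the fallen set and the 100 genes were defined anew under each alternative, so their members differ from those of the main fit. The test was checked on simulated data: in 20 draws for the rxeg1 comparison, 200 genes were changed by a log2 size of 1 or 2, with a mean of 3.95 false calls, a median of 0 and a highest number of 52. Each simulated library drew its deviations independently from all 14 groups, so correlation between mock and XEG1 libraries of a genotype was not simulated. Computations used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and version 1.17.8 of data.table; figures were drawn with matplotlib 3.10.9.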

Results

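Transcript levels were measured by RNA sequencing in 28 libraries from 12-day-old seedlings of Nicotiana benthamiana, a tobacco relative widely used to study plant immunity. Seedlings of 7 genotypes received a mock treatment or the XEG1 protein for 3 h, giving 14 groups of 2 libraries. XEG1 is a secreted glycoside hydrolase of the soybean pathogen Phytophthora sojae, RXEG1 is the receptor-like protein that recognises it at the plant cell surface, and SOBIR1 is a receptor kinase that works with many such receptor-like proteins. The genotypes were wild type, an rxeg1 knockout, a sobir1/sobir1-like knockout, and 4 lines that the labels describe as the rxeg1 knockout carrying an RXEG1syn construct behind the RXEG1 promoter. Of these lines, 2 carry RXEG1synΔCT and are called ΔCT line 1 and ΔCT line 2. The third, RXEG1synΔ90-95/Q786AK791AΔCT, also lacks residues 90 to 95 and has the substitutions Q786A and K791A, and is called the Δ90-95/Q786AK791A line. The fourth, RXEG1synΔ90-95/Δ786-792ΔCT, also lacks residues 90 to 95 and a second stretch given in its name, and is called the Δ90-95/Δ786-792 line.

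Values were TPM, a transcript abundance scaled to the same total in every library, for 59814 genes, of which 9517 were listed at 0 in all 28 libraries and 36777 had a mean of at least 1 TPM and were tested. Between 33443 and 37043 genes reached 1 TPM in a library, and the 20 most abundant genes of a library took 4.76% to 7.43% of its TPM. TPM keeps no sequencing depth, so the depth of each library is unknown. The Pearson correlation between the 2 replicates of a group, across genes, lay between 0.957 and 0.987. Gene identifiers came without names, so the RXEG1, SOBIR1 and SOBIR1-like genes were not checked in the knockout libraries and functional gene groups were not examined here.

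**Figure D1:**
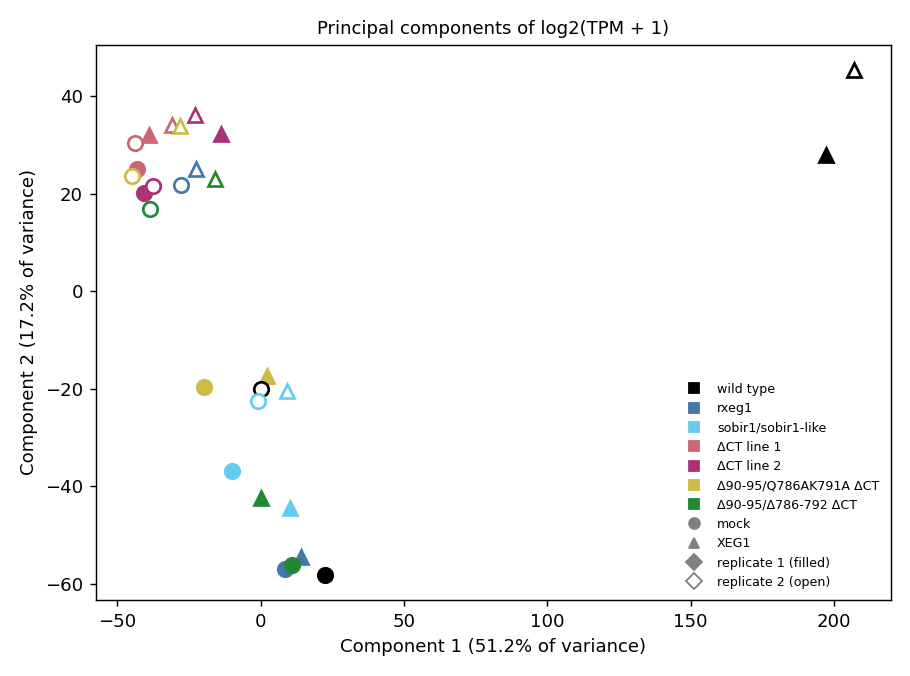
Principal components of log2(TPM + 1) over the 36777 tested genes. Each point is 1 library; colour gives the genotype, shape the treatment and fill the replicate. Both wild-type XEG1 libraries lie alone on component 1, which holds 51.2% of the variance. Component 2, with 17.2%, runs from -58.2 in wild-type mock replicate 1 to 45.4 in wild-type XEG1 replicate 2. All libraries of both ΔCT lines have positive values on it.

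The first question was which genes XEG1 changed in wild-type seedlings. The 3 h treatment changed 17782 of the 36777 tested genes (limma, adjusted p under 0.05), of which 4379 rose and 13403 fell. An absolute log2 change of at least 1 was reached by 2923 of the risen and 5549 of the fallen genes. The largest rise by the naming rule was in Niben101Scf00354g01012, from 0.471 ± 0.347 TPM in mock to 719 ± 69.8 TPM after XEG1 (SD, n = 2), a log2 change of 8.95 with a standard error of 0.33 and an adjusted p of 3.08e-13. Niben101Scf04787g02002 rose from 1.31 ± 0.146 to 1070 ± 3.09 TPM (log2 change 8.86, SE 0.40, adjusted p 3.69e-12). The largest fall was in Niben101Scf24053g00003, from 210 ± 29.9 to 2.76 ± 1.57 TPM (log2 change -5.87, SE 0.28, adjusted p 1.02e-11). Niben101Scf13085g00001 was second among the falls, with 37.5 and 34.1 TPM in the mock libraries and a listed 0 in both XEG1 libraries. It is also listed at 0 in 16 of the 24 libraries of the other genotypes, among them 1 mock library of rxeg1 whose replicate held 25.04 TPM, so no fold is given for it.

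The genes that rose in wild type held 8.34% ± 0.03 of all TPM in mock libraries and 36.9% ± 1.54 in XEG1 libraries (SD, n = 2). The TPM of a library have a fixed total, so the remaining genes lost that share. The median log2 change over all tested genes was -0.39. After dividing each library by a median ratio to the mean of all libraries, a scaling added after the data were examined, the median was 0.03 and 14376 genes were called, 8074 higher and 6302 lower. The share of higher genes among the calls was 24.6% without and 56.2% with this scaling. The scaling raises the wild-type log2 change of the genes, and 6295 of the 13403 fallen genes still fell with it.

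The next question was whether the response to XEG1 needs RXEG1 and SOBIR1. In the rxeg1 knockout limma called 0 genes, with 254 at an unadjusted p under 0.05, and in the sobir1/sobir1-like knockout 0 genes, with 558. In rxeg1 limma called 2 genes without its XEG1 replicate 1, and in sobir1/sobir1-like it called 2 genes with either of its XEG1 libraries left out and 6 when only the compared groups were fitted. With no filter 1 gene was called in each knockout. Under no difference 1839 genes would be at that unadjusted level. The counts in both knockouts lay below this, and the shortfall is not evidence that no gene responded. Deviations of mock and XEG1 libraries with the same replicate number correlated across genes at 0.73 in rxeg1 and 0.35 in sobir1/sobir1-like, which the fit did not model. With a block for the replicate number 0 genes were called in rxeg1 and 0 in sobir1/sobir1-like. This block removes only a shift common to all genotypes. It does not model a pairing within a genotype, which was not fitted, so these counts do not settle the effect of the correlations. Niben101Scf00354g01012 held 0.293 ± 0.148 TPM in rxeg1 after XEG1 and 1.03 ± 0.808 TPM in sobir1/sobir1-like (SD, n = 2), against 719 TPM in wild type. Niben101Scf24053g00003 stayed at 173 ± 35.9 and 144 ± 6.20 TPM in these genotypes. The 4379 genes that rose in wild type had a median log2 change of 1.39 there, 0.08 in rxeg1 (adjusted p 0.728) and 0.13 in sobir1/sobir1-like (adjusted p 0.381, rotation set test fry of limma over 12 tests). The risen set was defined anew under each alternative. With 1 library of the knockout left out its medians ranged from -0.0072 to 0.18 and from 0.066 to 0.20. With median-ratio scaling, where the set held 8074 genes, they were 0.03 and 0.08. On data simulated for the rxeg1 comparison, 48% of genes with a true log2 change of 1 were called among 36777 genes (31% to 73% over draws). For a change of 2 the share was 91.05% (81% to 99%). Each simulated library drew its deviations independently from all 14 groups. The simulation therefore held neither the correlation of 0.73 nor the spread of rxeg1, and its shares may not apply to the measured comparison.

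The response itself differed from wild type in both knockouts. For rxeg1, 10991 genes differed in their response, 7879 with a higher and 3112 with a lower log2 change than in wild type, and for sobir1/sobir1-like 10851 genes did, 7844 higher and 3007 lower. Higher response differences made up 71.7% and 72.3% of these calls, and 38.0% and 39.0% after median-ratio scaling, which called 9007 and 8864 genes. At Niben101Scf00354g01012 the response was lower than in wild type by a log2 difference of -8.89 in rxeg1 (SE 0.47, adjusted p 1.69e-10) and of -8.56 in sobir1/sobir1-like (SE 0.47, adjusted p 3.08e-10). The set of risen genes had a mean log2 response lower by -1.71 ± 0.14 in rxeg1 and by -1.64 ± 0.14 in sobir1/sobir1-like (SE, 14 residual degrees of freedom). The set was chosen for its rise in the same wild-type libraries, which favours a lower response elsewhere. These set differences are therefore descriptions and no test, and their SE ignores the choice. Leaving out wild-type XEG1 replicate 2 gave 7210 genes for sobir1/sobir1-like, and fitting only the compared groups gave 5981 genes for rxeg1.

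**Figure D2:**
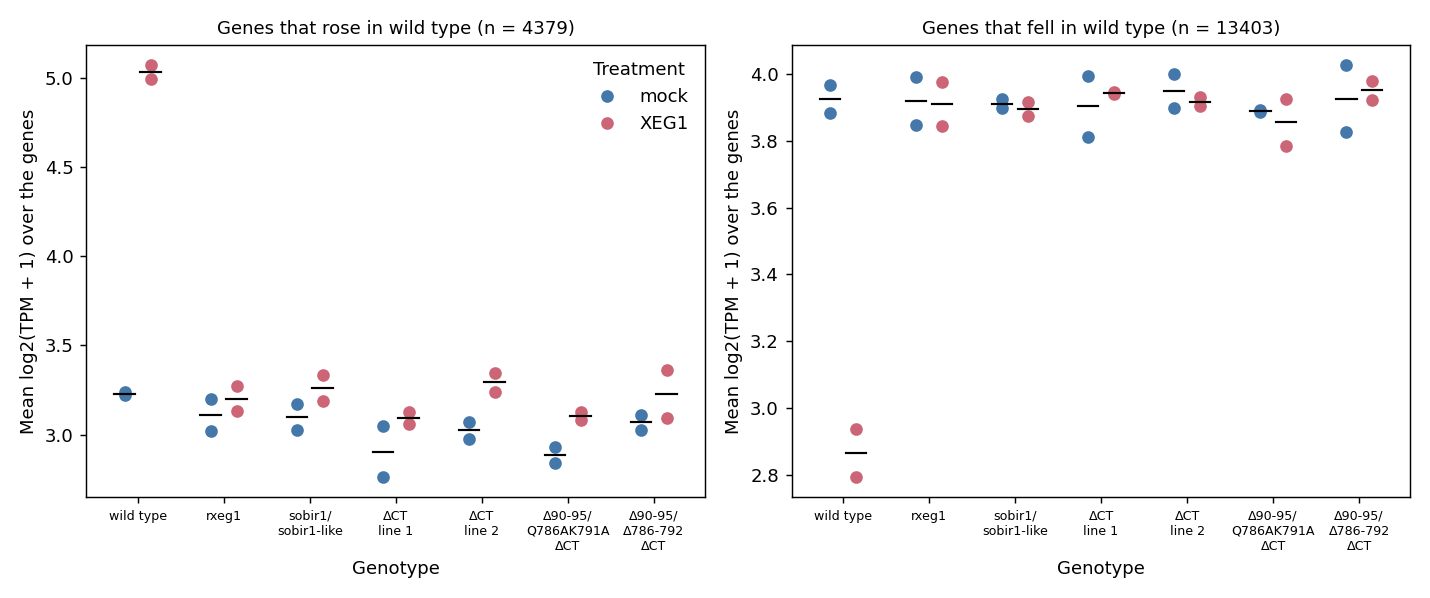
Mean log2(TPM + 1) per library over the 4379 genes that rose and the 13403 genes that fell after XEG1 in wild type, as points for the 2 libraries of each genotype and treatment, with the group mean as a line. The risen set moved from 3.23 in mock to 5.03 after XEG1 in wild type and stayed between 2.89 and 3.29 in all group means of the other 6 genotypes; for the fallen set, without scaling of the libraries, the wild-type means were 3.92 and 2.87.

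The construct lines were compared to ask whether the altered receptors restore the response to XEG1. No line of the series carries RXEG1syn without ΔCT, and the level of the constructs was not checked because identifiers came without names. A missing response therefore cannot be assigned to the alteration of the receptor itself. In ΔCT line 2, 23 genes rose and 0 fell, with 1500 genes at an unadjusted p under 0.05. All 23 also rose in wild type, where 2.74 would be shared by independent lists (two-sided Fisher's exact test across genes, p 5.26e-22, with genes not independent of each other). Their median log2 change was 2.04 in ΔCT line 2, ranging from 1.27 to 3.30, against 5.45 in wild type. Niben101Scf04362g07011 rose from 2.73 ± 0.05 to 37.3 ± 15.9 TPM (SD, n = 2) with a log2 change of 3.30 (SE 0.58, adjusted p 0.0463), while in wild type it went from 20.5 ± 2.63 to 1245 ± 31.3 TPM. Niben101Scf03993g05005 rose from 8.42 ± 1.76 to 79.9 ± 12.1 TPM (log2 change 3.11, SE 0.56, adjusted p 0.0463), against 34.0 ± 0.608 to 2659 ± 348 TPM in wild type. Both genes missed the threshold with a pseudocount of 0.1, with no filter, and with median-ratio scaling, under which 7 genes were called, while 6 were called with either of the first 2 settings. Fitting only the compared groups called 398 genes in this line. Its replicates lay closer together than those of rxeg1. The SD over genes of a library's deviation from its group mean was 0.14 in mock and 0.15 after XEG1, against 0.25 in both rxeg1 groups. The main fit shares its estimate of the spread among all groups, so its counts of calls are not directly comparable between genotypes. Without any 1 of the 4 libraries of this line 1 to 12 genes were called, of which at most 4 were among the 23: 2 without mock replicate 1, 1 without mock replicate 2, 1 without XEG1 replicate 1 and 12 without XEG1 replicate 2.

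In the other 3 construct lines limma called 0 genes. At an unadjusted p under 0.05 there were 553 genes in ΔCT line 1, 1290 in the Δ90-95/Q786AK791A line and 713 in the Δ90-95/Δ786-792 line, and median-ratio scaling gave 0, 2 and 0 calls. With no filter there were 7, 4 and 1 calls, with only the compared groups 1, 2 and 0, and with a pseudocount of 0.1 there were 1, 0 and 0. A block for the replicate number, which the labels do not tie to a shared batch, gave 0, 57 and 0 calls, and 27 in ΔCT line 2. The lack of calls in the Δ90-95/Q786AK791A line therefore depends on how the replicate number is treated. The Δ90-95/Q786AK791A line had 17 calls without XEG1 replicate 2 and 3 without mock replicate 1. ΔCT line 1 had 2 calls with either of its mock libraries left out and 1 without XEG1 replicate 2, and the Δ90-95/Δ786-792 line had 3 with either of its XEG1 libraries left out and 2 without mock replicate 2. Niben101Scf03993g05005 held 16.5 ± 11.1 TPM in mock and 91.5 ± 17.8 TPM after XEG1 in the Δ90-95/Q786AK791A line, 10.2 ± 3.17 and 32.0 ± 14.5 TPM in ΔCT line 1, and 11.3 ± 4.29 and 31.1 ± 24.7 TPM in the Δ90-95/Δ786-792 line (SD, n = 2). The 23 genes called in ΔCT line 2 had a median log2 change of 1.45 in the Δ90-95/Q786AK791A line, 1.00 in ΔCT line 1, 0.74 in the Δ90-95/Δ786-792 line and 0.64 in rxeg1, none of them a test because the genes were chosen in ΔCT line 2. Over the 4379 genes risen in wild type the median log2 change was 0.14 in ΔCT line 1, 0.17 in ΔCT line 2, 0.16 in the Δ90-95/Q786AK791A line and 0.14 in the Δ90-95/Δ786-792 line, each with an adjusted p of 0.381 (fry, 12 tests). The risen and fallen sets were defined anew under each alternative. With 1 library of the line left out the risen-set medians ranged from 0.018 to 0.28, 0.12 to 0.23, 0.13 to 0.21 and 0.011 to 0.26 in the same order. With median-ratio scaling, where the risen set held 8074 genes, they were 0.05, 0.08, 0.08 and 0.05. The 13403 fallen genes had median changes between -0.01 and 0.04 in the 6 genotypes other than wild type, each with an adjusted p of 0.962, and between -0.093 and 0.12 with 1 library left out, and in rxeg1 the median (0.0010) and the mean (-0.0083) differed in sign.

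Against wild type, every construct line differed in its response. The counts were 11796 genes for ΔCT line 1 (8809 with a higher and 2987 with a lower log2 change), 11217 for ΔCT line 2 (8286 and 2931), 10986 for the Δ90-95/Q786AK791A line (8017 and 2969) and 11645 for the Δ90-95/Δ786-792 line (8616 and 3029). Higher differences were 74.7%, 73.9%, 73.0% and 74.0% of these calls, and 38.7%, 36.5%, 37.5% and 38.1% with median-ratio scaling, which called 9103, 8527, 8609 and 9107 genes. At Niben101Scf00354g01012 the log2 response was lower than in wild type by -8.56, -7.74, -7.66 and -8.97 in the same order (SE 0.47 each, adjusted p 2.75e-10, 1.31e-09, 1.42e-09 and 1.43e-10). The risen set had mean differences of -1.61, -1.53, -1.59 and -1.64, each ± 0.14 (SE). They are no test, because the set was chosen for its rise in the same wild-type libraries. All 6 comparisons with wild type share its 4 libraries. Leaving out wild-type XEG1 replicate 2 gave 7318 genes for the Δ90-95/Q786AK791A line, and fitting only the compared groups gave 6742 for the Δ90-95/Δ786-792 line.

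Against the rxeg1 knockout, limma found 0 genes with a different response in any construct line. The unadjusted p was under 0.05 for 188 genes in ΔCT line 1, 536 in ΔCT line 2, 396 in the Δ90-95/Q786AK791A line and 289 in the Δ90-95/Δ786-792 line. Leaving out 1 library called at most 2 genes in ΔCT line 1, ΔCT line 2 and the Δ90-95/Δ786-792 line and at most 5 in the Δ90-95/Q786AK791A line, and fitting only the compared groups called 3, 4, 1 and 1 in the order of the unadjusted counts. With no filter 1 gene was called in ΔCT line 1. Over the risen set the median log2 difference from rxeg1 was 0.07, 0.11, 0.08 and 0.06 in the same order, each with an adjusted p of 0.798 (fry, 9 tests, a test added after the data were examined). Among the constructs, the response called 0 genes between the ΔCT lines (280 at an unadjusted p under 0.05), 0 for the Δ90-95/Q786AK791A line (284) and 0 for the Δ90-95/Δ786-792 line (296) against the mean of both ΔCT lines, and 0 between these last 2 lines (495). Leaving out 1 library called at most 2, 5, 2 and 4 genes in these comparisons, no filter called 2 between the ΔCT lines, and fitting only the compared groups called 1 for the Δ90-95/Q786AK791A line against both ΔCT lines. The median standard error of a response difference was 0.33 log2 units, or 0.29 against the mean of both ΔCT lines, which limits what these comparisons could show. Thus the calls in ΔCT line 2 are not shown to differ from rxeg1 or from ΔCT line 1. ΔCT line 2 alone was not compared with the Δ90-95/Q786AK791A or the Δ90-95/Δ786-792 line.

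The last question was how the genotypes differed from wild type without XEG1. In mock-treated seedlings 11 genes differed in rxeg1 (4 higher, 7 lower), 11 in sobir1/sobir1-like (5 and 6) and 20 in the Δ90-95/Δ786-792 line (11 and 9). Niben101Scf02937g06005 was higher in rxeg1, at 9.09 ± 1.79 against 1.77 ± 1.28 TPM in wild type (log2 difference 1.94, SE 0.26, adjusted p 0.00446; SD, n = 2). Niben101Scf02435g01015 was lower in rxeg1, at 0.667 ± 0.0818 against 8.17 ± 1.06 TPM (log2 difference -2.46, SE 0.22, adjusted p 4.81e-05). Neither difference was particular to rxeg1. Limma called both genes in sobir1/sobir1-like in the same direction, with log2 differences of 1.81 (adjusted p 0.0116) and -2.34 (adjusted p 5.16e-05). In sobir1/sobir1-like the largest difference was at Niben101Scf03628g01009, with 0.106 ± 0.150 against 19.8 ± 0.629 TPM (log2 difference -4.24, SE 0.30, adjusted p 9.24e-07). Fitting only the compared groups left 1 gene for rxeg1, which was neither of those named, 108 for sobir1/sobir1-like and 6 for the Δ90-95/Δ786-792 line. With no filter there were 22, 23 and 31 genes in the same order, and median-ratio scaling gave 21 for sobir1/sobir1-like. In the order rxeg1, sobir1/sobir1-like and Δ90-95/Δ786-792 line, the counts were 1, 3 and 4 without wild-type mock replicate 1, 6, 5 and 9 without wild-type mock replicate 2, and 1, 2 and 4 without the genotype's own mock replicate 1. Without its mock replicate 2 they were 5, 7 and 22.

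Larger mock differences were called in ΔCT line 1, with 4970 genes (2336 higher, 2634 lower), the Δ90-95/Q786AK791A line, with 3810 (1576 and 2234), and ΔCT line 2, with 1652 (996 and 656). Niben101Scf01578g00012 was higher in ΔCT line 1, at 13.8 ± 6.10 against 1.80 ± 0.0836 TPM (log2 difference 2.33, SE 0.42, adjusted p 0.00276). Niben101Scf04053g02006 was lower in the Δ90-95/Q786AK791A line, at 4.18 ± 2.86 against 87.1 ± 50.8 TPM (log2 difference -4.07, SE 0.63, adjusted p 0.00175). In ΔCT line 2 Niben101Scf05124g00001 was lower, at 0.385 ± 0.00438 against 12.8 ± 0.604 TPM (log2 difference -3.31, SE 0.50, adjusted p 0.00533). Limma also called this gene lower in the Δ90-95/Δ786-792 line (log2 difference -3.60, SE 0.50, adjusted p 0.00487), so the difference was not particular to ΔCT line 2. On component 2 both mock libraries of ΔCT line 1 lay at 25.2 and 30.4 and those of ΔCT line 2 at 20.2 and 21.6, against -58.2 and -20.02 in wild type. The wild-type XEG1 libraries lay at 27.9 and 45.4, so this component does not separate genotypes alone. The replicates of rxeg1 mock lay at -57.0 and 21.8, those of the Δ90-95/Q786AK791A line at -19.7 and 23.6, and those of the Δ90-95/Δ786-792 line at -56.0 and 16.9. The counts rest on single libraries: without wild-type mock replicate 1 they were 1102 in ΔCT line 1, 622 in the Δ90-95/Q786AK791A line and 18 in ΔCT line 2, without wild-type mock replicate 2 they were 2410, 1811 and 51, without the line's own mock replicate 2 they were 37, 182 and 6, and without its mock replicate 1 they were 5801, 2485 and 591. With median-ratio scaling 60.3% higher calls in ΔCT line 2 became 46.8%, of 1192 genes, and fitting only the compared groups gave 7477 genes there.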

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

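The test of the fixed TPM total was chosen after the result was seen. The response to XEG1 differed from wild type in each of the other 6 genotypes by the test of the difference itself: 10991 genes in rxeg1, 10851 in sobir1/sobir1-like, 11796 in ΔCT line 1, 11217 in ΔCT line 2, 10986 in the Δ90-95/Q786AK791A line and 11645 in the Δ90-95/Δ786-792 line. These 6 comparisons share the wild-type libraries and are not independent of each other. The biological difference named by the design is the genotype, with RXEG1 or SOBIR1 and SOBIR1-like missing or RXEG1 altered. At Niben101Scf00354g01012, 719 TPM in wild type stood against 0.293 TPM in rxeg1 and 1.03 TPM in sobir1/sobir1-like.

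In wild type more genes fell (13403) than rose (4379), and without scaling higher response differences outnumbered lower ones in all 6 comparisons with wild type. With median-ratio scaling both splits turned, to 56.2% higher calls in wild type and to between 36.5% and 39.0% in the 6 comparisons, while 6295 of the 13403 fallen genes still fell. The fixed total of TPM may contribute to this surplus: as the risen genes grew from 8.34% to 36.9% of TPM, the rest together fell by a log2 change of -0.54, next to a median-ratio shift of -0.51. Both values would be much the same if the other transcripts had truly fallen, and TPM hold no absolute amounts, so the fixed total cannot be told apart from a fall in RNA per seedling.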

How the results depend on the processing

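Of the alternatives below, median-ratio scaling was chosen after the data were examined. Settings chosen beforehand that need counts (other size factors, a filter on counts and a second count-based tool) were not run, because the values are TPM. The count of genes called in the wild-type response lay between 12475 and 19621 under every alternative except the log2 threshold of 1. Of named genes, 484 of the values under alternatives kept their direction and side of the threshold, 98 no longer passed and 0 reversed; 75 of the 98 came from leaving out a library. The cause of the shifts was not tested except where fewer libraries or genes enter by construction. TPM hold no depth, so what depth limits is unknown, and the number of libraries limits the precision.

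With a pseudocount of 0.1, the XEG1 response called 1 gene in ΔCT line 1 and 6 in ΔCT line 2. With no filter on low values it called 1 gene in rxeg1, 1 in sobir1/sobir1-like, 7 in ΔCT line 1, 6 in ΔCT line 2, 4 in the Δ90-95/Q786AK791A line and 1 in the Δ90-95/Δ786-792 line, the response difference called 1 between ΔCT line 1 and rxeg1 and 2 between the ΔCT lines, and the mock difference called 22 in rxeg1, 23 in sobir1/sobir1-like and 31 in the Δ90-95/Δ786-792 line. A log2 threshold of 1 left 8472 genes in the wild-type response, 7304, 7222 and 7747 in the response differences of ΔCT line 2, the Δ90-95/Q786AK791A line and the Δ90-95/Δ786-792 line from wild type, and mock differences of 1775 in ΔCT line 1, 608 in ΔCT line 2 and 1376 in the Δ90-95/Q786AK791A line, by construction. Median-ratio scaling left 7 genes in the response of ΔCT line 2, gave 2 in the Δ90-95/Q786AK791A line and a mock difference of 21 in sobir1/sobir1-like.

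In fits of only the compared groups, the XEG1 response called 6 genes in sobir1/sobir1-like, 1 in ΔCT line 1, 398 in ΔCT line 2 and 2 in the Δ90-95/Q786AK791A line. The response difference from wild type called 5981 genes in rxeg1 and 6742 in the Δ90-95/Δ786-792 line; that from rxeg1 called 3 in ΔCT line 1, 4 in ΔCT line 2, 1 in the Δ90-95/Q786AK791A line and 1 in the Δ90-95/Δ786-792 line, and that of the Δ90-95/Q786AK791A line from the mean of the ΔCT lines called 1. The mock difference called 1 gene in rxeg1, 108 in sobir1/sobir1-like, 7477 in ΔCT line 2 and 6 in the Δ90-95/Δ786-792 line. These fits estimate the spread from fewer libraries and only from the compared groups, and the groups differed in spread. The SD over genes of a library's deviation from its group mean was 0.14 (mock) and 0.15 (XEG1) in ΔCT line 2. It was 0.25 in both rxeg1 groups, and 0.26 and 0.22 in the Δ90-95/Δ786-792 line. The main fit shares its estimate of the spread among all groups, so its counts of calls are not directly comparable between genotypes.

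With the replicate block, the XEG1 response called 57 genes in the Δ90-95/Q786AK791A line, and the mock difference called 18 in sobir1/sobir1-like and 3552 in ΔCT line 2; other counts stayed within 1.5 times. The block is a single shift common to all genotypes, and no pairing within a genotype was fitted. The labels do not say that a number marks a shared batch. Deviations of the mock and XEG1 libraries with the same number correlated across genes at 0.17 in wild type, 0.73 in rxeg1, 0.35 in sobir1/sobir1-like, -0.016 in ΔCT line 1, -0.0034 in ΔCT line 2, 0.50 in the Δ90-95/Q786AK791A line and 0.54 in the Δ90-95/Δ786-792 line, and 50 of 91 pairs of groups were above 0.1.

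Leaving out 1 library at a time, the XEG1 response called 0 to 2 genes in rxeg1, 0 to 2 in sobir1/sobir1-like, 0 to 2 in ΔCT line 1, 1 to 12 in ΔCT line 2, 0 to 17 in the Δ90-95/Q786AK791A line and 0 to 3 in the Δ90-95/Δ786-792 line. The response difference from wild type ranged from 7210 to 10129 in sobir1/sobir1-like and from 7318 to 11069 in the Δ90-95/Q786AK791A line. Against rxeg1 it ranged from 0 to 2 in ΔCT line 1, ΔCT line 2 and the Δ90-95/Δ786-792 line and from 0 to 5 in the Δ90-95/Q786AK791A line. Between the ΔCT lines it was 0 to 2, against their mean 0 to 5 in the Δ90-95/Q786AK791A line and 0 to 2 in the Δ90-95/Δ786-792 line, and between these last 2 lines 0 to 4. The mock difference ranged from 1 to 6 in rxeg1, 2 to 7 in sobir1/sobir1-like, 37 to 5801 in ΔCT line 1, 6 to 591 in ΔCT line 2, 182 to 2485 in the Δ90-95/Q786AK791A line and 4 to 22 in the Δ90-95/Δ786-792 line.

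Medians of the wild-type sets, which were defined anew under each alternative, were small in the other genotypes, and some changed sign without passing the test. In the main fit the risen set had positive medians in each of them, from 0.08 to 0.17. Between 70.6% and 80.7% of its members were higher, against 51.3% to 66.2% of all tested genes. Across tested genes the log2 changes correlated with those of wild type at 0.17 to 0.44 (Pearson r). No set passed the test in the main fit. For the fallen genes in rxeg1 the median was 0 with no filter, -0.0057 with sets defined by a log2 change of at least 1 and -0.028 with median-ratio scaling, which also gave -0.016 in ΔCT line 1 and -0.027 in the Δ90-95/Δ786-792 line. Leaving out 1 library, the risen genes in rxeg1 ranged from -0.0072 to 0.18, and the fallen genes from -0.084 to 0.090 in rxeg1, -0.035 to 0.021 in sobir1/sobir1-like, -0.030 to 0.12 in ΔCT line 1, -0.053 to 0.043 in ΔCT line 2, -0.093 to 0.086 in the Δ90-95/Q786AK791A line and -0.082 to 0.12 in the Δ90-95/Δ786-792 line.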

Other observations

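The analyses of the 100 genes, of genes that separate genotypes, and the tests of activity beyond rxeg1 and of a growth or handling difference were chosen after the results were seen. The test of carry-over was not, and that of the construct or line was set before its own values were seen but after other forms of it had been run. The 100 genes with the largest rise in wild type (median log2 change 6.21) gave a sharper view of the construct lines than the whole risen set. In ΔCT line 2 they rose by a median of 0.88, with 92 of 100 higher (fry, adjusted p 0.000689 over 6 tests), and in the Δ90-95/Q786AK791A line by 0.74, with 90 higher (adjusted p 0.00153), and both rises kept an adjusted p under 0.05 without any 1 library of these lines. The medians were 0.38 in ΔCT line 1 (82 higher, adjusted p 0.0797), 0.33 in sobir1/sobir1-like (85, 0.0979), 0.29 in the Δ90-95/Δ786-792 line (77, 0.156) and 0.19 in rxeg1 (74, 0.266). Of all tested genes, 66.2%, 51.3%, 62.9% and 54.8% were higher in these genotypes in the same order. The share was 56.7% in ΔCT line 2 and 53.7% in the Δ90-95/Q786AK791A line, so the counts of higher genes are not directly comparable between genotypes. Picked anew with a pseudocount of 0.1, the 100 genes had medians of 1.66 in ΔCT line 2, 1.37 in the Δ90-95/Q786AK791A line, 0.69 in ΔCT line 1, 0.67 in sobir1/sobir1-like, 0.40 in rxeg1 and 0.29 in the Δ90-95/Δ786-792 line. Leaving out 1 library of the genotype moved the smaller medians both ways: from 0.15 (adjusted p 0.479, without mock replicate 1) to 0.55 (0.0545, without XEG1 replicate 1) in sobir1/sobir1-like, from 0.23 (0.263, without XEG1 replicate 2) to 0.57 (0.0449, without XEG1 replicate 1) in ΔCT line 1, and from 0.038 (0.732, without XEG1 replicate 2) to 0.53 (0.0389, without XEG1 replicate 1) in the Δ90-95/Δ786-792 line. Without its mock replicate 2 sobir1/sobir1-like had a median of 0.53 with an adjusted p of 0.0309, and in rxeg1 the medians lay between 0.15 and 0.21. None of 9 differences between the genotypes passed: against rxeg1 the median difference was 0.76 in ΔCT line 2 (adjusted p 0.111) and 0.56 in the Δ90-95/Q786AK791A line (adjusted p 0.146).

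Some genes followed the genotype in both treatments; they were chosen after their values were seen. Niben101Scf03628g01009 lay between 0 and 0.212 TPM in the 4 sobir1/sobir1-like libraries and between 5.24 and 22.2 TPM in the other 24. Niben101Scf01926g00002 lay between 1.07 and 4.07 TPM in the 4 libraries of the Δ90-95/Q786AK791A line and between 12.7 and 31.1 TPM elsewhere. In that line 55 genes were above and 53 below every other library, where 1.80 each way would be reached by chance order. The counts above and below were 137 and 467 in wild type, 78 and 14 in ΔCT line 1, 18 and 1 in ΔCT line 2, 10 and 5 in sobir1/sobir1-like, 7 and 1 in rxeg1, and 3 and 1 in the Δ90-95/Δ786-792 line.

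The 4 wild-type and 4 rxeg1 libraries did not overlap at 3190 of 36777 genes (8.67%, with 2.86% by chance order), and at 10 of these the gap was at least 1 log2 unit. At these 10 genes all 4 libraries of ΔCT line 2 lay on the rxeg1 side each time, those of the Δ90-95/Q786AK791A and Δ90-95/Δ786-792 lines at 8 genes each and on the wild-type side at 0. ΔCT line 1, which the labels also place in the rxeg1 knockout, lay on the rxeg1 side at 4 genes and on the wild-type side at 4. The sobir1/sobir1-like libraries, which are not labelled as rxeg1 knockouts, lay on the rxeg1 side at 6 and on the wild-type side at 3. At Niben101Scf02435g01015, for example, ΔCT line 1 held 10.03 to 16.5 TPM, against 6.30 to 8.93 in wild type, 0.600 to 1.11 in rxeg1 and at most 0.877 in the other 3 construct lines. At Niben101Scf02316g03001 ΔCT line 1 held 9.90 to 11.9 TPM, against 3.70 to 11.7 in wild type and 25.6 to 34.2 in rxeg1. The sobir1/sobir1-like libraries held 0.505 to 1.16 TPM at the first gene and 27.4 to 32.9 TPM at the second, so neither gene marks the rxeg1 knockout alone. With a gap of 0.5 there were 70 genes, of which ΔCT line 1 lay on the rxeg1 side at 39 and on the wild-type side at 7, ΔCT line 2 at 48 and 3, the Δ90-95/Q786AK791A line at 52 and 1, the Δ90-95/Δ786-792 line at 39 and 3, and sobir1/sobir1-like at 21 and 12.

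The small rise of the 100 genes in ΔCT line 2 and the Δ90-95/Q786AK791A line was weighed against carry-over as a technical explanation. Carry-over of wild-type XEG1 RNA would give each gene the same share of its wild-type level, but the shares, with medians of 0.938% and 0.646%, were gene-specific and correlated between replicates across the 100 genes (Spearman rho 0.755 and 0.780). This argues against carry-over as the only cause. A part from carry-over cannot be excluded, because a gene-specific rise with carry-over added would correlate too. A weak activity of the altered receptors is a candidate explanation, but whether ΔCT line 2 exceeds the rxeg1 knockout, which lacks the construct, stays open at an adjusted p of 0.111. These genes also had a positive median in rxeg1, so an effect of XEG1 outside RXEG1 may contribute as well and was not tested.

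For the many mock differences in ΔCT line 1, the Δ90-95/Q786AK791A line and ΔCT line 2, a growth or handling difference and the construct or line itself were weighed. Replicate 2 minus replicate 1 was alike in rxeg1 and the Δ90-95/Δ786-792 line in both treatments (Pearson r across genes from 0.51 to 0.73), and along this shift the called genes moved by 16.6%, 8.58% and 18.6% of their median mock difference. Across these genes the shift and the mock difference correlated (Pearson r 0.46, 0.21 and 0.50), but the size of such a shift between a line and wild type was not measured, so how much it accounts for stays open, and an earlier bound of 50% on its share was replaced by its direction alone after these values were seen. A difference of the line itself should return in its XEG1 libraries against those of rxeg1, which enter none of the mock comparisons. There 46.0%, 44.8% and 32.2% of the median mock difference was found, between 21.2% and 60.04% over all pairs of libraries. The direction was the same at 96.0%, 94.8% and 88.5% of the called genes, and at 79.7%, 72.7% and 74.9% of all tested genes. An earlier form of the test counted genes called against the rxeg1 mock libraries, and 0.523%, 10.2% and 0% of the called genes returned. That form counts genes passing a threshold, so its values cannot be set against shares of the mock difference. Because called genes are selected for large mock differences, shares of 32.2% to 46.0% leave open whether the line is the whole cause. Growth conditions that differ between lines cannot be told apart from the construct because each line was sampled as its own group.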
